A study of Mus musculus with 8 samples.

How the data were processed

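Total RNA from mouse testis was hybridised to Affymetrix expression arrays, per the labels. The 8 arrays fall into 4 groups of 2, named here by the word after Mus musculus in each sample's title: castaneus, domesticus, musculus and ssp. The labels call the 2 arrays of each group technical replicates, and the number of animals behind each RNA sample is not given in the sources used here. Every p-value from limma's tests of single probe sets or from fry therefore measures only the spread between technical replicate arrays. Camera compares the genes of a list with the other genes, so its p-values at a preset correlation rest on the spread across genes. Fisher, binomial and permutation p-values are also taken over genes or probe sets. No p-value measures the spread between animals. Every call compares the RNA samples on these arrays, not the mouse populations they came from. The labels do not say what ssp stands for, and it is treated here only as a group name.

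The values the authors deposited are linear intensities, 1 per probe set and array, for 12422 probe sets with no control probe sets among them. A probe set is a group of short probes that together report 1 transcript. All values were positive, and the mean after trimming 2% at each end lay between 495.7 and 496.7 on every array, so each deposited array had already been scaled to a common mean intensity. The method that summarised the probes, its version and the scaling step are not given in the sources used here. The deposited intensities were used without further scaling. Array medians ran from 151 to 183 intensity units. All 8 value columns were matched to a sample by name, and the number of arrays limits the precision of every value.

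Values below the 10th percentile of all intensities, 18.7, were raised to that floor, and log2 was taken. Between 7.39% and 13.1% of an array's probe sets lay at the floor. Where every array of a group was at the floor, the fold against it is a lower bound and is written as "at least". A probe set was tested if it reached its array's 40th percentile on at least 2 of the 8 arrays, which left 8874 probe sets. Group values are geometric mean intensities, and their SD is on the log2 scale with n = 2 arrays.

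Gene symbols came from the platform annotation and were updated through the Entrez gene number to a RefSeq gene table of assembly GRCm38.p6, which was used only for names, chromosomes and gene order. Of the 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none, and 10817 were matched to the table. Genes are named only from probe sets with 1 symbol. A suffix such as _f, _s, _g, _i or _r before _at in a probe set's identifier marks, in the manufacturer's naming, probes that can match related transcripts or that met fewer design rules.

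Differences were tested with limma 3.58.1 in R 4.3.3, by a linear model with 1 mean per group over all 8 arrays and moderated by empirical Bayes. The fit had 4 residual degrees of freedom, with 2.34 prior degrees of freedom and a prior SD of 0.36 on the log2 scale. A probe set differed among the 4 groups if the moderated F test gave a Benjamini-Hochberg adjusted p under 0.05 and the group means spanned at least 1 on the log2 scale. The 6 pairs of groups were tested by moderated contrasts with the same thresholds, adjusted within each pair. A probe set was called specific to a group if it passed in the same direction against each of the other 3.

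Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, on each group against the mean of the other 3. Of 35 lists of testis cell types, other cell types and pathways, 31 had at least 5 tested genes, and p-values were adjusted over all 124 tests. The 4 contrasts sum to 0, so a list high in 1 group tends to be low in others. Each gene was represented by its tested probe set with the highest mean. For lists the number of members passing limma's threshold is given over all probe sets tested and adjusted over the list alone. Camera with an estimated correlation judges a list on the 4 residual degrees of freedom of the fit, and limma's fry tests each list without reference to other genes.

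The groups, tests, gene lists and naming rule were fixed before the data were examined. The rule names, for each group, up to 12 higher and 12 lower specific genes whose 2 arrays both lie beyond the other 6. It names the 3 genes with the largest difference in each direction for each pair, and the 10 genes with the largest range of group means. It also names, for each called list, up to 4 members that passed the threshold in the list's direction, or the 2 largest as values only. Other probe sets of a named gene are mentioned where they disagree.

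The fit was tested on simulated data with the real means and the moderated spreads, as independent normal noise. The simulation held no correlation between genes and no replicate effect, so it follows the model's own assumptions. It cannot show the share of false calls on the real arrays. For a simulated difference between domesticus and musculus, with 200 of 8874 probe sets changed in each of 5 runs, 2% of 2-fold, 45.6% of 4-fold, 77.6% of 8-fold and 94% of 16-fold changes were called, and 4.2% of the calls were false. Differences of about 2-fold are therefore mostly missed with 2 arrays per group. The alternatives tried were quantile normalization, median centring, other floors and filters, other variance models and thresholds, a replicate block, each array left out in turn, and other list tests.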

Results

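Testis transcripts were measured in RNA from 4 groups of house mice labelled castaneus, domesticus, musculus and ssp, with 2 technical replicate arrays of each. The series asks which genes are expressed differently in testis among these mice. Of 12422 probe sets, 8874 were bright enough to be tested. Values are intensities as deposited, and folds are ratios of geometric means over the 2 arrays of a group.

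On average, replicate arrays resembled each other more than arrays of different groups did, by a small margin and with 1 exception. The Pearson correlation of log2 intensities between the 2 arrays, taken across probe sets, was 0.911 in castaneus, 0.916 in domesticus, 0.914 in musculus and 0.877 in ssp. Between 77.5% and 84.3% of probe sets agreed within 2-fold between replicates, lowest in ssp. The root mean square log2 difference averaged 0.86 over the 4 replicate pairs and 0.99 over the 24 array pairs from different groups. The exception was ssp replicate 1, at 0.96 from its own replicate but 0.92 from both castaneus replicate 1 and domesticus replicate 1. These arrays share its replicate number. On average-linkage clustering, the arrays of every group joined each other before any other array or cluster. The castaneus and domesticus pairs joined before the 2 ssp arrays joined each other. The musculus pair was next to join them, and the ssp pair was last. With the replicate spread subtracted, the distance between groups ran from 0.41 for castaneus and ssp to 0.55 for castaneus and musculus.

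**Figure D1:**
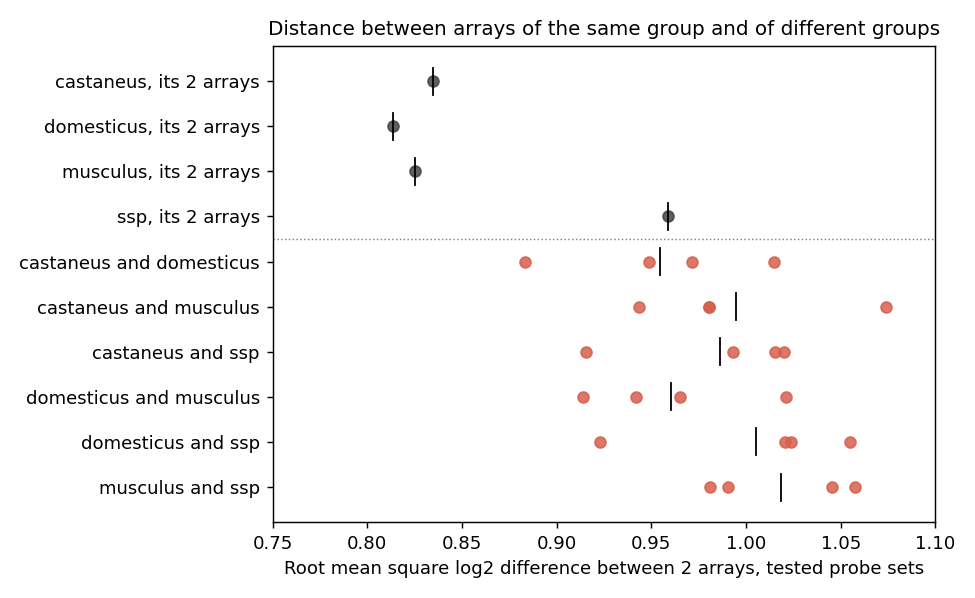
Root mean square log2 difference (x axis) between 2 arrays over the tested probe sets, for arrays of the same group (dark points) and of different groups (red points), with the mean of each row as a black line. Replicate arrays lie between 0.81 and 0.96, and arrays of different groups between 0.88 and 1.07, so the distance between the ssp replicates falls within the range between groups.

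The widest ranges among the 4 groups were those of Igkv6-23, Agt and Faap20, followed by Pdk3 and Ckmt2. Igkv6-23, an immunoglobulin kappa variable gene, ranged from 64.6 in musculus to 5880 in castaneus, a 91.1-fold span (limma, adjusted p = 0.0339). The probe sets ranked here for Igkv6-23, Faap20 and Ighm carry a suffix for probes that can match related transcripts or met fewer design rules. Agt, which encodes angiotensinogen, spanned 45.8-fold with its highest value in domesticus. Pdk3, a pyruvate dehydrogenase kinase, and Ckmt2, the mitochondrial creatine kinase of striated muscle, each spanned 33.0-fold, with their lowest values in musculus and ssp respectively. Faap20, a partner of the Fanconi anaemia core complex, spanned at least 34.4-fold and was at the floor in castaneus. Ces1c, a carboxylesterase, spanned 28.5-fold, the uncharacterised 1700097N02Rik 26.1-fold, Ncf1 of the phagocyte NADPH oxidase 24.1-fold and Ighm, the immunoglobulin mu heavy chain, 23.7-fold. Tnnc1, troponin C of slow and cardiac muscle, spanned at least 26.9-fold. The lowest values of Ces1c (20.5, with 1 of 2 arrays at the floor) and Ncf1 (19.55), both in domesticus, lay next to the floor of 18.7, so the size of these folds rests on the floor. In total 156 probe sets of 132 named genes, 1.76% of those tested, differed among the groups, and 1415 had an unadjusted p under 0.05. Leaving out 1 array lowered this count to between 9, without either castaneus array, and 55, without ssp replicate 1, with 39 without ssp replicate 2, 10 and 14 without domesticus replicates 1 and 2, and 13 and 11 without musculus replicates 1 and 2. Other settings of the filter and the variance model gave 31 to 383 probe sets.

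The castaneus RNA stood apart by 4 genes that were higher and 5 that were lower than in each other group. Ighm, by 1 of its probe sets, was 11 to 18.0-fold higher, at 466.5 against 25.9 to 42.3 in the others. Hey1, a transcriptional repressor downstream of Notch, was 5.49 to 8.39-fold higher at 2445 (SD 0.07 log2, n = 2). Cnga3, a subunit of the cyclic nucleotide-gated channel of cone cells, was 4.09 to 5.43-fold higher, and Rsu1, the Ras suppressor protein, 3.26 to 4.94-fold higher.

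Faap20 was at the floor on both castaneus arrays and at least 14.1-fold lower than in any other group. Zfp62, a zinc finger gene, was 12.5 to 22.6-fold lower, with 1 of the 2 castaneus arrays at the floor. Cyb5r4, a cytochrome b5 reductase, was 5.30 to 6.51-fold lower. Glul, glutamine synthetase, was 4.81 to 5.77-fold lower and Klhdc2, a substrate receptor of a ubiquitin ligase, 3.55 to 4.18-fold lower. The adjusted p was at most 0.0477 for these 9 genes, with log2 standard errors of 0.23 to 0.37. A second probe set of Glul, at 483.1 in castaneus against 610.3 to 926.3, and of Faap20, at 75.7 against 146.5 to 248.1, was also lowest in castaneus, by less, and did not pass. Of the 6 other Ighm probe sets, 3 were lower in castaneus than in domesticus and musculus, at 26.6, 37.6 and 35.4 against 490.1, 197.9 and 174.1 in domesticus, and the first 2 of these 3 differed among the groups. The remaining 3 read 363.5, 106.5 and 78.4 in castaneus and 298.5, 63.9 and 65.9 in domesticus and did not pass. In all, 11 probe sets were specific to castaneus, 4 higher and 7 lower, and none was specific by limma in any of the 8 fits that left out 1 array. Median centring of the arrays gave 3 higher and 3 lower, and other settings gave 2 to 33.

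Among the transcripts higher in domesticus than in each other group, those of angiotensinogen and of the gut and brain peptide cholecystokinin stood furthest apart. Agt was 30.9 to 45.8-fold higher, at 2297 (SD 0.22 log2, n = 2) against 50.1 to 74.3 elsewhere. Cck was 11.3-fold higher than in ssp and at least 19.8-fold higher than in castaneus and musculus, where both arrays were at the floor. Pla2g12a, a secreted phospholipase A2, was 10.3 to 15.6-fold higher at 7480. Nxph1, a neurexin ligand, was 5.08-fold higher than in castaneus and at least 8.74-fold higher than in musculus.

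Psma3, an alpha subunit of the 20S proteasome, was 5.02 to 6.68-fold higher in domesticus, and Dnajb2, an Hsp40 co-chaperone, 4.38 to 5.27-fold higher. Cox6b2, the testis isoform of a cytochrome c oxidase subunit, was 13.4 to 22.6-fold lower, at 653.9 against 8739 to 14750. Serpinb6a, a serine protease inhibitor, was 4.26 to 10.3-fold lower and Qrich1, a glutamine-rich protein gene, 4.15 to 5.65-fold lower. The adjusted p was at most 0.0433 for these 9 genes. Cox6b2 differed by 1 of its 3 probe sets alone: the brightest read 20030 in domesticus and 24460 to 29030 in the others and did not pass (adjusted p = 0.559). The other Pla2g12a probe set read 220 in domesticus and 109.8 to 187.4 in the others and did not pass either. These 9 probe sets, 6 higher and 3 lower, were all that were specific to domesticus. With 1 array left out there were 3 without ssp replicate 1, 1 without ssp replicate 2, 1 without musculus replicate 1 and 0 in the other 5 fits, and other settings gave 1 to 25.

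Among the transcripts higher in musculus than in each other group, those of prostaglandin D synthase and insulin-like growth factor 2 stood furthest above the next highest group. Ptgds, the lipocalin-type prostaglandin D2 synthase, was 9.71 to 16.8-fold higher, at 19230 (SD 0.24 log2, n = 2). Its 2 other probe sets also differed among the groups and were highest in musculus, at 8884 and 8920. Igf2, an imprinted growth factor, was 8.54 to 12.8-fold higher at 5196. Fkbp1b, which binds calcium release channels, was 7.02 to 7.69-fold higher.

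Myh7, the slow and cardiac myosin heavy chain, was 4.74 to 17.6-fold higher in musculus. Lst1, a leukocyte transcript, was 3.72 to 5.57-fold higher and Ap5s1, of the AP-5 adaptor complex, 3.47 to 4.32-fold higher. Among 12 genes that were lower, Pdk3 fell furthest, to 73.5 against 1767 to 2429, a 24.0 to 33.0-fold difference with a log2 standard error of 0.26. Myl10, a myosin light chain, was 15.9 to 21.2-fold lower. Arsa, the lysosomal arylsulfatase A, was 8.76 to 18.8-fold lower, Atxn10 8.27 to 9.87-fold and Fyttd1, an mRNA export factor, 7.94 to 8.76-fold. Snx4, a sorting nexin, Calml4, Nmur1, the neuromedin U receptor, and Srsf2, a splicing factor, were lower, with smallest folds of 6.96, 6.11, 5.87 and 5.54 against any other group. Arcn1, a coatomer subunit, Defa23, a defensin, and Adsl, of purine synthesis, were lower, with smallest folds of 5.14, 4.64 and 4.44 and with 1 of the 2 musculus arrays at the floor for Defa23.

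The adjusted p was at most 0.0463 for the 18 named musculus genes. A second probe set did not pass for Atxn10 (adjusted p = 0.961), Srsf2 (0.951), Arcn1 (0.639), Arsa (0.446) and Myh7 (0.975). Those of Atxn10 and Srsf2 did not fall, at 195.1 and 627.1 in musculus against 178.6 to 215.8 and 569.8 to 685.6 in the others. Those of Arcn1 and Arsa were lowest in musculus by less, at 100.9 and 81.2 against 111.7 to 184.4 and 106 to 186.4. That of Myh7 went the other way, lowest in musculus at 96.05 against 102.2 to 129. In all 19 probe sets were specific to musculus, 7 higher and 12 lower. An identifier suffix for probes that can match related transcripts or met fewer design rules was carried by 7 of these 19, 1 of the 11 castaneus, 3 of the 9 domesticus and 5 of the 11 ssp probe sets, that of Sry among them. Leaving out 1 array gave 6 without ssp replicate 1, 3 without castaneus replicate 2, 1 without ssp replicate 2 and 0 in the other 5 fits, and other settings gave 8 to 54.

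In the ssp RNA, 3 genes were higher and 8 lower than in each other group. Lalba, alpha-lactalbumin, was 12.2-fold higher than in musculus and at least 15.7-fold higher than in domesticus, at 293.6 (SD 0.05 log2, n = 2). Atp2a1, the calcium pump of fast muscle, was 5.64 to 6.14-fold higher. Sry, the testis-determining gene of the Y chromosome, was 3.54 to 4.92-fold higher, at 227.4 against 46.2 to 64.2.

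Ckmt2 was 15.1 to 33.0-fold lower in ssp, at 36.1 (SD 0.12 log2, n = 2) against 543.4 to 1192. H2-Aa, a class II histocompatibility chain, was 9.24 to 15.8-fold lower. Itgae, an integrin of intraepithelial lymphocytes, was 7.04 to 7.82-fold lower, Aldh2, mitochondrial aldehyde dehydrogenase, 6.83 to 9.24-fold and Tkt, transketolase, 6.69 to 19.9-fold. Abca1, a cholesterol exporter, was 6.20 to 12.9-fold lower, Syce2, of the synaptonemal complex that joins meiotic chromosomes, 4.62 to 5.5-fold and Cask, a membrane scaffold kinase, 3.83 to 4.95-fold. The adjusted p was at most 0.0465 for these 11 genes. A second probe set read 948.1 in ssp and 856.2 to 1513 in the others for Itgae, and 213.9 against 229.1 to 399.5 for Abca1, and neither passed. Of the 2 other Aldh2 probe sets, 1 was lowest in musculus, at 104.7, and read 368.3 in ssp, and 1 read 188.8 in ssp against 612.5 to 1102 without passing. A second Ckmt2 probe set read 40.5 in ssp against 131.3 to 162.1 and did not pass. With 1 array left out, 1 probe set was specific to ssp without musculus replicate 1 and 0 by limma in the other 7 fits, and other settings gave 2 to 21.

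**Figure D2:**
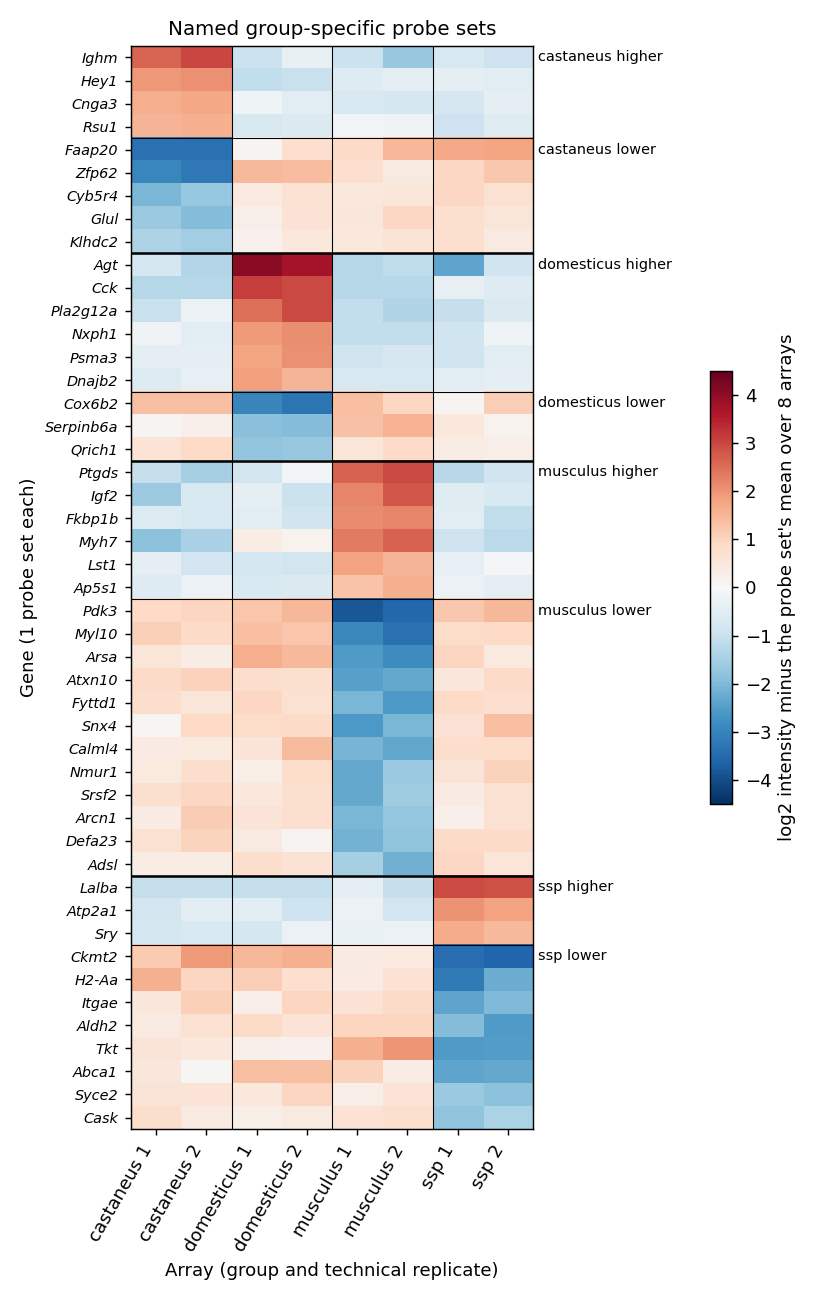
Log2 intensity of each named group-specific probe set (rows, 1 per gene) on each of the 8 arrays (columns), as the difference from that probe set's mean over the 8 arrays, red above and blue below it. Both arrays of the named group lie beyond the other 6 for each gene, by the rule that chose them, and the largest deviation is 4.05.

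Between pairs of groups, the largest differences again fell on a small set of genes. Castaneus and domesticus differed at 60 probe sets, 19 higher in castaneus and 41 higher in domesticus. Cox6b2 was 22.6-fold, Ces1c 21.4-fold and Tnnc1 18.2-fold higher in castaneus, with 1 of the 2 domesticus arrays at the floor for both Ces1c and Tnnc1. Agt, 1700097N02Rik and Zfp62 were 30.9, 26.1 and 22.6-fold higher in domesticus. Castaneus and musculus differed at 84 probe sets, 40 higher in castaneus and 44 in musculus. Igkv6-23 was 91.1-fold (log2 difference 6.51, SE 0.70), Ighg3, an immunoglobulin gamma chain, 26.7-fold and Pdk3 24.0-fold higher in castaneus. The Ighm probe set that was low in castaneus was 23.7-fold, Faap20 at least 23.4-fold and Srms, a non-receptor tyrosine kinase, 19.1-fold higher in musculus, with 1 of the 2 castaneus arrays at the floor for Srms. The Ighg3 probe set named here carries such a suffix, as does that of Igkv6-23. A second Ighg3 probe set was also highest in castaneus, at 1574, while another read 342.1 in domesticus and 57.2 in castaneus.

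Castaneus and ssp differed at 31 probe sets, 17 higher in castaneus and 14 in ssp. Ckmt2, H2-Aa and the Ighm probe set specific to castaneus were 33.0, 15.8 and 12.7-fold higher in castaneus. Faap20 was at least 34.4-fold, Zfp62 17.7-fold and Lalba 15.6-fold higher in ssp, with 1 of the 2 castaneus arrays at the floor for both Zfp62 and Lalba. Domesticus and musculus differed at 66 probe sets, 38 higher in domesticus and 28 in musculus. Agt, Pdk3 and Myl10 were 34.4, 33.0 and 21.2-fold higher in domesticus. Erbb3, a neuregulin receptor, was 21.7-fold, Cox6b2 19.4-fold and Stac, an adaptor protein, 15.5-fold higher in musculus, with 1 of the 2 domesticus arrays at the floor for Erbb3.

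Domesticus and ssp differed at 61 probe sets, 41 higher in domesticus and 20 in ssp. Agt was 45.8-fold, Ckmt2 33.0-fold and Snn, stannin, 20.1-fold higher in domesticus, and Ces1c, Tnnc1 and Ncf1 were 28.5, 25.6 and 24.1-fold higher in ssp. Musculus and ssp differed at 87 probe sets, 54 higher in musculus and 33 in ssp. Syt11, a synaptotagmin, was 22.9-fold, Tkt 19.9-fold and Adh1, an alcohol dehydrogenase, 18.6-fold higher in musculus. Pdk3 was 32.6-fold, Tnnc1 at least 26.9-fold and Myl10 15.9-fold higher in ssp. Leaving out any 1 of the 8 arrays gave 0 to 67 calls per pair by limma, and 17 of these 48 counts were 0, with 704 to 1240 probe sets at an unadjusted p under 0.05 over the 48. Only without ssp replicate 1 or 2 did castaneus with musculus (67 and 65) and domesticus with musculus (55 in both) stay near their counts. Over the 6 pairs, the counts were 87 to 223 with a trended and robust variance model, 79 to 185 with the filter at the 60th percentile, 4 to 32 without a filter and 9 to 30 when tested against 1.5-fold. With the replicate number as a block they were 6 to 63. With only the 4 arrays of a pair in the fit, limma called 0 in each of the 6 pairs, with 827 to 1145 at an unadjusted p under 0.05.

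**Figure D3:**
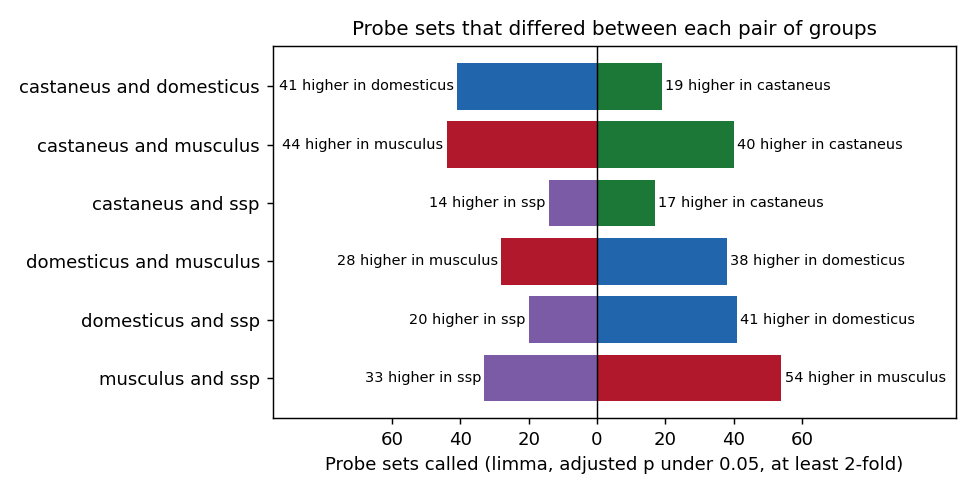
Probe sets called between each pair of groups (limma, adjusted p under 0.05 and at least 2-fold), as bars from 0 to the right for those higher in the first named group and to the left for those higher in the second. Counts run from 31 between castaneus and ssp to 87 between musculus and ssp, and more of the calls are higher in domesticus in each of its 3 comparisons.

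Leydig cell transcripts, from the cells of the testis that make testosterone, were higher in the musculus RNA than in the mean of the other groups. All 15 measured markers had a positive difference, with a median log2 difference of 0.94, or 1.92-fold (camera, adjusted p = 1.96e-09). The call was lost when camera estimated the correlation between genes (adjusted p = 0.243 with an estimated correlation). The estimate, -0.028, lay below the preset 0.01, so in that test the call was lost on the 4 residual degrees of freedom. Taken between technical replicate arrays, the estimate cannot show how far Leydig genes vary together between animals. Of the 15 markers, 3 rose over all probe sets tested and 8 adjusted over the list alone. Against single groups, 15 were higher in musculus than in castaneus, 12 than in domesticus and 13 than in ssp. Insl3 and Hsd11b1 differed between the musculus replicates, at 7.776 and 6.479 and at 8.322 and 6.974 log2, and were not higher than in ssp. Cyp17a1, which makes androgen precursors, was 3.8-fold higher (SE 0.21 log2, adjusted p = 0.0214). Hsd3b1, a steroid dehydrogenase, was 3.29-fold higher (adjusted p = 0.0345) and Star, which brings cholesterol into mitochondria, 2.93-fold higher (adjusted p = 0.0308). Dimmer second probe sets of Cyp17a1 and Star did not follow, at 102.2 and 152.8 in musculus against 147.3 to 172 and 139.5 to 142.3 in the others.

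The same Leydig list was lower in ssp, with a median log2 difference of -0.43 and 13 of 15 markers negative (adjusted p = 5.27e-05). That call too was lost (adjusted p = 0.388 with an estimated correlation). Star was 2.98-fold lower (adjusted p = 0.0404) and Gstm1, a glutathione transferase abundant in Leydig cells, 2.80-fold lower (adjusted p = 0.0484), the 2 markers that fell over all probe sets tested, against 7 adjusted over the list alone. A second Gstm1 probe set read 458.1 in ssp and 324.3 to 459.3 in the others, and the second Star probe set 142.3 against 139.5 to 152.8. In castaneus the median was -0.57, with 14 of 15 markers negative (adjusted p = 0.00297). This call was lost as well (adjusted p = 0.457 with an estimated correlation), and 0 markers fell over all probe sets tested by limma, against 1 adjusted over the list alone. The largest differences were in Hsd3b6, at 53.6 in castaneus and 116.1 to 321.1 elsewhere, and Cyp11a1, the cholesterol side-chain cleavage enzyme, at 268.3 against 529.2 to 1730. Against single groups, in tests chosen after the results were seen, the castaneus list passed only against musculus (adjusted p = 6.13e-09, and adjusted p = 0.206 with an estimated correlation). Its median was -0.43 against domesticus (adjusted p = 0.0726) and 0.27, the other way, against ssp (adjusted p = 0.415).

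Cholesterol synthesis transcripts, a list that shares 0 genes with the Leydig list, were also higher in musculus. All 15 members were positive, with a median log2 difference of 0.52 (camera, adjusted p = 0.000832). With an estimated correlation, here -0.00124 and so below the preset 0.01, the call was lost (adjusted p = 0.452 with an estimated correlation). By limma 0 members passed over all probe sets tested and 3 adjusted over the list alone. Mvd, mevalonate diphosphate decarboxylase, read 239.7 in musculus and 34.2 to 84.0 elsewhere, and Dhcr7, the last enzyme of the pathway, 378.5 against 80.6 to 178.7. In castaneus the median was -0.31, with 11 of 15 members negative (adjusted p = 0.0476), and the call was lost (adjusted p = 0.796 with an estimated correlation). There 0 members passed by limma, adjusted either way. Idi1, isopentenyl diphosphate isomerase, read 639.7 in castaneus and 1129 to 1519 elsewhere, and Sc5d was at the floor in castaneus and read 24.2 to 50.6 elsewhere, with musculus replicate 2 and ssp replicate 2 also at the floor. Against single groups the castaneus list passed only against musculus (adjusted p = 0.000451, and adjusted p = 0.552 with an estimated correlation), with medians of -0.22 against domesticus (adjusted p = 0.256) and -0.03 against ssp (adjusted p = 0.815). The musculus list did not pass against domesticus alone (adjusted p = 0.0726). With the replicate number as a block the castaneus call was lost (camera, adjusted p = 0.066). The castaneus call was also lost without either castaneus array (adjusted p = 0.108 and 0.191), either musculus array (0.0978 and 0.0823), domesticus replicate 1 (0.0661) or ssp replicate 1 (0.158), and with quantile normalization (0.0514), fry (0.171) or all probe sets of the list genes (0.0778).

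Macrophage and immune cell markers moved with the Leydig list in musculus and ssp. In musculus 13 of 14 were positive, with a median log2 difference of 0.51 (camera, adjusted p = 0.000832). That shift was lost (adjusted p = 0.826 with an estimated correlation, here 0.328). By limma 0 rose over all probe sets tested and 3 adjusted over the list alone. The complement genes C1qc and C1qa read 952.4 and 729.4 in musculus, against 97.8 to 394.6 and 193.9 to 353.5 elsewhere. In ssp the median was -0.35, with 10 of 14 negative (adjusted p = 0.0221), and this call was lost (adjusted p = 0.826 with an estimated correlation). H2-Aa was the 1 marker that fell over all probe sets tested, by 12.2-fold (adjusted p = 0.0232), against 3 adjusted over the list alone. Other class II chains of the list did not fall alike. H2-Eb1 read 8.991 and 7.845 log2 on the ssp arrays against 6.682 to 8.776 elsewhere, and H2-Ab1 5.797 and 7.691 against 6.805 to 8.786. With the replicate number as a block the ssp call was lost (camera, adjusted p = 0.066). The ssp call was also lost without castaneus replicate 1 (adjusted p = 0.108), musculus replicate 1 (0.0662) or ssp replicate 1 (0.236), without the filter on low values (0.0502) and by fry (0.217), and fry also ended the musculus call (0.196). Against single groups, the musculus list did not pass against domesticus (adjusted p = 0.424) nor the ssp list against castaneus (adjusted p = 0.766).

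**Figure D4:**
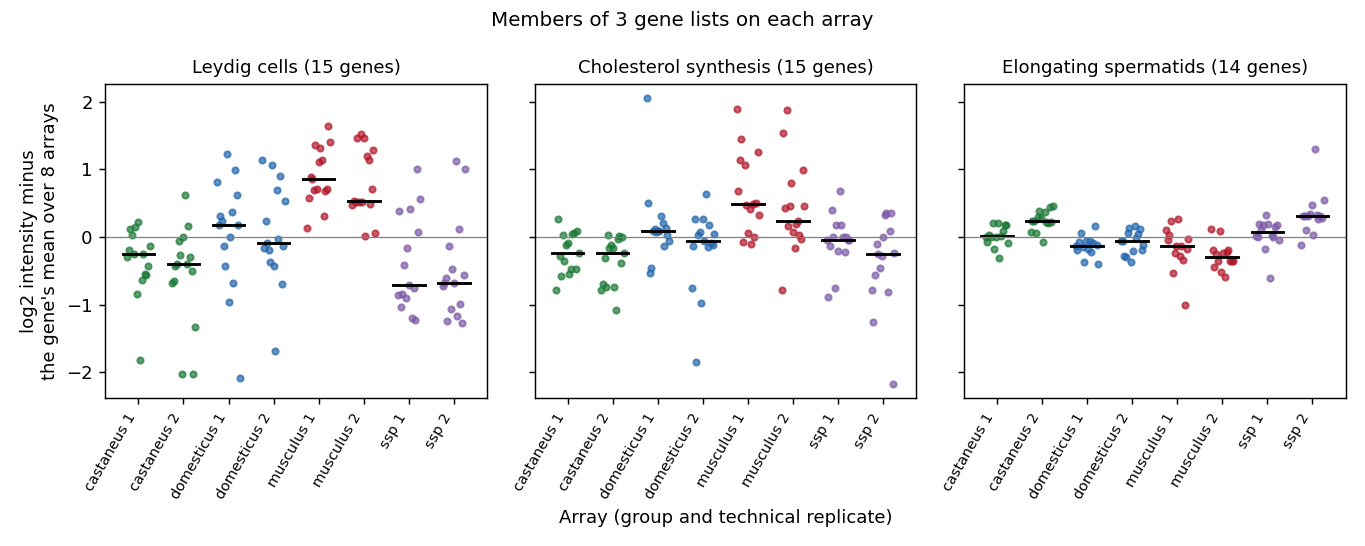
Log2 intensity of each member of 3 gene lists on each of the 8 arrays, as the difference from that gene's mean over the 8 arrays, with the median of the list on each array as a black line. The Leydig medians are 0.86 and 0.53 on the musculus arrays and -0.71 and -0.68 on the ssp arrays, while the medians of the elongating spermatid markers lie between -0.30 and 0.31 on all 8.

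No difference between X-linked and autosomal genes was detectable in the share that differed among the groups. Of 179 tested genes on the X chromosome 3 differed, or 1.68%, against 128 of 6388 autosomal genes, or 2.0%. The odds ratio was 0.834 with a 95% interval of 0.168 to 2.53 (two-sided Fisher's exact test, p = 1). With the filter at the 60th percentile the X-linked odds ratio was 0.363 (Fisher's exact p = 0.174).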

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

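None of the named differences and called lists changed direction under the alternatives run for them. For the group-specific genes this is no support, because they were chosen with both arrays of the group beyond all others. Leaving out an array, the offset and the balanced replicate block could not reverse their direction. The fit without the ssp arrays was chosen after seeing the data. Pairs are listed in the order castaneus with domesticus, castaneus with musculus, castaneus with ssp, domesticus with musculus, domesticus with ssp and musculus with ssp, and group-specific counts in the order castaneus, domesticus, musculus and ssp. Counts of calls moved under most settings, and the cause was not tested except where the setting itself changes how many probe sets or arrays are used. Folds of dim probe sets also rest on the floor, since signal near background has no measured size.

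Without a filter on low values, with more probe sets tested, 31 probe sets differed among the groups, the pairs gave 4, 32, 8, 29, 21 and 28, the specific counts were 2, 1, 8 and 3, and the ssp macrophage call was lost (adjusted p = 0.0502). The stricter filter at the 60th percentile gave 309, pairs of 128, 185, 79, 129, 130 and 146, specific counts of 23, 21, 43 and 21, and mean distances of 0.831 between and 0.638 within groups. A floor at the 25th percentile gave 243, pairs of 98, 140, 61, 89, 102 and 144, and specific counts of 19, 17, 30 and 17. An offset in place of the floor gave distances of 0.850 and 0.727, and 183 probe sets. Trended and robust empirical Bayes gave 383, pairs of 167, 223, 87, 175, 153 and 196, and specific counts of 33, 25, 54 and 16. Testing against 1.5-fold with limma's treat gave pairs of 9, 30, 13, 29, 24 and 19 and specific counts of 3, 2, 8 and 3, and was not run for the differences among all 4 groups. With only the 2 groups compared in the fit, limma called 0 in all 6 pairs (827 to 1145 at an unadjusted p under 0.05). Without the ssp arrays, castaneus and domesticus differed at 18 probe sets.

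Median centring gave 35 for castaneus and domesticus, 19 for castaneus and ssp, and specific counts of 6 for castaneus (3 higher, 3 lower) and 7 for ssp. One probe set per gene gave 7 specific to castaneus. Quantile normalization gave 157 probe sets and lost the castaneus cholesterol call (adjusted p = 0.0514). Removing the fold threshold left every count as it was. The X-linked against autosomal odds ratio was 0.363 with the stricter filter.

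The replicate number used as a block gave 42 probe sets, 40 of them among the 156, pairs of 8, 63, 6, 43, 22 and 29, specific counts of 2, 2, 13 and 2, and lost the castaneus cholesterol and ssp macrophage calls (adjusted p = 0.066 for both). Correlations between the deviations of same-numbered arrays were 0.149, 0.0855, 0.155, 0.105, 0.171 and 0.0263 over the 6 pairs. Not all were above 0.1, so the numbers were not taken to pair the samples. All 6 were positive, however, so a shared effect of the replicate number is not excluded. Castaneus replicate 1 correlated at 0.887 with musculus replicate 2 and at 0.871 with musculus replicate 1. Castaneus replicate 2 correlated at 0.880 with musculus replicate 2 and at 0.849 with musculus replicate 1. Same-numbered arrays correlated at 0.895 and 0.882 in castaneus with domesticus, against 0.886 and 0.865 for differently numbered arrays. In the same order, castaneus with ssp gave 0.888 and 0.873 against 0.864 and 0.864. Domesticus with musculus gave 0.870 and 0.896 against 0.887 and 0.866. Domesticus with ssp gave 0.883 and 0.868 against 0.850 and 0.865, and musculus with ssp 0.867 and 0.862 against 0.849 and 0.875. The replicate number itself had 0 calls by limma.

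With an estimated correlation camera called 0 of 124 list tests, with 7 at an unadjusted p under 0.05. Adjusted p was then 0.243, 0.388 and 0.457 for the Leydig list in musculus, ssp and castaneus, 0.452 and 0.796 for cholesterol synthesis in musculus and castaneus, and 0.826 for the macrophage list in both groups. The estimates were -0.028 for the Leydig, -0.00124 for the cholesterol and 0.328 for the macrophage list, against the preset 0.01. Only the macrophage estimate exceeded the preset, so the Leydig and cholesterol calls were lost on the 4 residual degrees of freedom. The estimates are taken between technical replicate arrays and cannot show correlation between animals. By fry the castaneus cholesterol (adjusted p = 0.171) and both macrophage calls (0.196 in musculus, 0.217 in ssp) were lost. With all probe sets of the list genes the castaneus cholesterol call was lost (adjusted p = 0.0778). With the preset correlation the 3 Leydig calls and the musculus cholesterol and macrophage calls held under quantile normalization, without the filter, with the replicate block, with all probe sets and with each array left out.

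With 1 array left out, the lone array of its group is assumed to vary like the other groups. The count among groups was then 9 to 55, of which 8 and 38 were among the 156, and the pairs gave 0 to 19, 0 to 67, 0 to 8, 0 to 55, 0 to 17 and 0 to 26. Specific counts were 0 in all 8 fits for castaneus, 0 to 3 for domesticus, 0 to 6 for musculus and 0 to 1 for ssp. Adjusted p ranged from 0.0193 to 0.191 for castaneus cholesterol synthesis and from 0.00182 to 0.236 for ssp macrophage markers. It stayed between 2.49e-09 and 1.46e-06 for the Leydig list in musculus. Of the 60 named differences, 58 passed with the offset, 51 with quantile normalization, and 26 with the replicate block. With 1 array left out, 56 to 58 of them were tested in each fit and 2 to 20 passed, and 0 passed in all the fits that tested them.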

Other observations

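The count of lower against higher calls relative to domesticus, the list tests between pairs of groups, and the Leydig comparisons with single cell types and with macrophages, were chosen after the results were seen, as were the genes named in the first 2 paragraphs. No list of germ cell transcripts passed in any group against the mean of the others. Markers of elongating spermatids, the cells that pack sperm DNA with protamines, had a median log2 difference of -0.26 in musculus, with 12 of 14 negative (camera, adjusted p = 0.0842), and of 0.27 in ssp, with 13 of 14 positive (adjusted p = 0.102). Between musculus and ssp directly, 13 of the 14 were lower in musculus, with a median of -0.42 (adjusted p = 0.0341, and adjusted p = 0.857 with an estimated correlation). Prm3, a protamine family gene, read 9796 in musculus and 17350 to 19450 in the other groups without passing (adjusted p = 0.174). Round spermatid and meiotic spermatocyte markers had medians of -0.11 and -0.03 in musculus, with adjusted p of 0.511 and 0.959, and the Sertoli cell list had a median of -0.19 (adjusted p = 0.463).

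Hba-a1, an alpha globin chain of red blood cells, read 15040 in musculus and 1997 to 2943 in the other groups, and did not pass limma (6-fold, adjusted p = 0.145). Alas2, the haem synthesis enzyme of red cells, read 675.8 in musculus against 208.6 to 289.3, while Slc4a1, the red cell anion exchanger, read 28.0 against 21.1 to 142.6 and was highest in ssp. Only 3 red blood cell genes were measured, too few for the list test. Of 4 Y-linked genes measured, Sry was higher in ssp, while Kdm5d, Eif2s3y and Uba1y did not pass between ssp and the mean of the others by limma (adjusted p = 0.995, 0.595 and 0.774). Among 11 imprinted genes, Igf2 rose in musculus (adjusted p = 0.0186), and Meg3, at 152.3 in musculus and 31.3 to 108.3 elsewhere, did not pass (adjusted p = 0.0849).

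A lower share of germ cells in the musculus RNA would raise the markers of every other testis cell type alike, and the macrophage median of 0.51 (13 of 14 positive, with 0 passing alone by limma, 3 adjusted over the list alone, and the list call lost at adjusted p = 0.826 with an estimated correlation and 0.196 by fry) and the negative elongating spermatid differences, which did not pass, go the same way. Yet the Leydig median exceeded the pooled median of 31 Sertoli, peritubular and endothelial markers, 0.07, by 0.87 (95% bootstrap interval over genes, 0.69 to 1.58), and that of all 45 with the macrophage markers by 0.735 (0.55 to 1.39). It exceeded the Sertoli median, -0.19, by 1.13 (0.69 to 1.77) and the peritubular median by 0.86 (0.36 to 1.54), which argues against fewer germ cells as the whole cause, while the intervals against endothelium (0.67, -0.04 to 1.5) and macrophages (0.43, -0.30 to 1.12) include 0. Sequence variants under the probes would lower the signal in groups other than domesticus, from which laboratory mouse sequence mostly descends. Yet the Leydig median was 0.77 higher in musculus than in domesticus (interval 0.54 to 1.44), which argues against variants for that comparison. It does not bear on the lower Leydig values in castaneus and ssp, to which variants could still contribute. All of these bootstrap intervals take genes as independent draws and hold no spread between arrays or animals. More Leydig cells, more steroid synthesis per cell, or a part played by fewer germ cells stay open. So do age, season and dissection of the animals behind the RNA. With an estimated correlation camera loses the Leydig list call (adjusted p = 0.243).

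More probe sets were lower than higher when each group was compared with domesticus. Of the 148 probe sets that differed from domesticus in at least 1 group, 95 were lower and 53 higher, or 64.2% lower (95% exact interval 55.9% to 71.9%, two-sided exact binomial p = 0.000698, adjusted p = 0.00279 over the 4 groups taken as reference). All comparisons with domesticus share its 2 arrays, and some genes have several probe sets. The calls are therefore not independent, and the interval and p overstate the evidence. The share lower than the reference was 46.4% for castaneus, 55% for musculus and 40.2% for ssp, where calls leaned the other way (exact binomial p = 0.0292, adjusted p = 0.0584, with 38.5% and 38.1% under quantile normalization and median centring), and for domesticus it was 64.7% with quantile normalization and 64.8% with median centring. This is what variants under probes designed from laboratory mouse sequence could give, but it also follows if more transcripts are high in the domesticus RNA. Other probe sets of the same gene moved the same way by at least 0.5 times the called log2 difference in 22.8% of 57 cases (exact interval 12.7% to 35.8%) for calls lower than domesticus and in 31.4% of 35 cases for higher calls (two-sided Fisher's exact p = 0.464). The interval and p take the cases as independent, which they are not. Many come from the immunoglobulin genes Ighm and Ighg3, with some pairs of probe sets counted in both directions or for more than 1 group. The shares without these genes were not computed. Probe variants and true differences therefore cannot be told apart here, with so few genes, 26 and 15, having a second probe set.

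A further hypothesis was that genes that differ neighbour each other on the chromosomes, as a divergent segment would produce. Of 6571 tested genes with a position, 132 differed, and 2 adjacent pairs both differed, against a mean of 2.59 over 10000 shuffles (permutation p = 0.737). The pairs were Adh1 with Adh4 and Aldh9a1 with Mgst3, named after their values were seen. The count gives no sign of clustering.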
